A study of Mus musculus with 4 samples.

How the data were processed

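The series measured chromatin accessibility in mouse neutrophils by ATAC-seq, in 2 KO (Morrbid-deficient) and 2 WT libraries, grouped and numbered by their titles. The submitters' processing notes name bcl2fastq 2.16.0, Trimmomatic 0.32, BWA, MACS2 2.1.0, DiffBind, R 3.1.1 and HOMER, and the mm9 build, without giving their order or role. Mapping and peak calling parameters, duplicate removal, any shift of reads for the Tn5 insertion offset, the rule for consensus peaks and whether peaks were called per library are not given in the sources used here. If reads were not shifted, peak edges would move by a few bases, which matters little at a median peak length of 571 bp. Multi-copy sequence can be counted differently with other mapping filters. The deposited table of consensus peaks gives a normalised signal per library for each peak, together with HOMER-style annotation of the nearest TSS, the region class and repeats, per the file headers. All per-sample columns matched a title and none was left unused.

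The deposited signal was inspected first. All 94380 values were whole multiples of 1 step per library within a tolerance of 0.001 (largest deviation 7.3e-07), so each value is a whole number of steps, with 1 step per library. The step was 0.883 in KO replicate 1, 0.693 in KO replicate 2, 1.47 in WT replicate 1 and 1.39 in WT replicate 2. Dividing by these steps gave the reads in peaks, from 3577922 to 7930547 per library, with median reads per peak of 136, 175, 86 and 91 in the same order. Taking a step as 1 read, these numbers served for depth, counting intervals, the comparison of replicates and thinning. The values were kept as signal, since the lowest values do not fix the size of 1 read in every column, and no count model was used. The widths listed in the table exceeded end minus start by 2 for all 23595 peaks, so starts may be off by 1 or 2 bases. Coordinates are printed as deposited, in mm9. No genome sequence was used here. Gene IDs of 23568 of 23595 peaks matched a RefSeq gene table of a later assembly, GRCm38.p6, which was used for names only and linked the listed Gm14005 to Morrbid.

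Differences between KO and WT were tested per peak with limma 3.58.1 in R 4.3.3 (two-sided, empirical Bayes with a mean-variance trend) on log2(signal + 1), with genotype as the only term and Benjamini-Hochberg adjustment over all peaks. Peaks with adjusted p below 0.05 were called. A filter on a mean signal above 1 removed no peak. A pseudocount of 1 shrinks the fold change of weak peaks. Promoter peaks were those within 1000 bp of a TSS or annotated as promoter, 1 per gene, the nearest to the TSS (8777 genes). Gene lists were tested on these with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, for lists with at least 3 promoter peaks, adjusted over the 20 such lists of 27. The lists covered pro- and anti-apoptotic BCL2 family genes, death receptors and caspases, chromosome 2 neighbours, primary, secondary and mature neutrophil genes, myeloid transcription factors, cytokine receptors, Polycomb subunits and developmental targets, interferon, inflammatory, immediate early, cell cycle and control genes, and markers of 11 cell types. Annotation classes were compared by Fisher's exact test against all tested peaks. Ratios of reads carry exact conditional 95% intervals. Figures were drawn with matplotlib 3.10.9.

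The lists, tests, alternatives and the rule for named peaks were fixed before the data were examined. The rule took every peak of Morrbid and Bcl2l11, the promoter peaks of the chromosome 2 neighbours, the 12 called peaks of lowest p in each direction with separated groups, up to 4 members of lowest p per list, and the 5 called promoters of largest change in each direction. The fixed representative of Bcl2l11 was the peak nearest a TSS. On simulated libraries with the real peaks' means and depths, with 200 of 23595 peaks changed, the KO against WT test recovered 43% of 1.5-fold and 89% of 2-fold changes with 1 false call, at a simulated dispersion of 0.005. This dispersion was a set minimum, the same in both genotypes. No trend with strength and no preparation effect tied to genotype was simulated. False calls in the real libraries may therefore be more frequent. A simulated shift of 0.5 (log2) in the 32 promoters of mature neutrophil genes was recovered by camera (adjusted p = 8.09e-64). Of 19 other lists 1 was called, the neutrophil markers, which share members. With so low a dispersion and no trend simulated, this does not show how large a shift the list tests would detect in the real libraries.

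Replicates were compared before averaging. Across peaks, which are not independent replicates, Pearson's correlation of log2 signal was 0.9812 for the KO pair, 0.9593 for the WT pair and 0.9375 to 0.9486 between genotypes. A chi-square of reads gave 2.214 per degree of freedom for the KO pair and 2.538 for the WT pair, so no pair agreed within sampling noise and all 4 libraries were counted. The alternatives were other scalings, cyclic loess, the replicate number as a block, a stricter filter, other pseudocounts and thresholds, limma without trend, each library left out, and 4 settings chosen after seeing the data: thinning to 3577922 reads per library, removal of trends with peak strength and with the number of peaks within 500 kb, leaving out peaks in annotated repeats, and camera with an estimated correlation under cyclic loess.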

Results

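Chromatin accessibility was measured by ATAC-seq in neutrophils sorted from mouse bone marrow. Neutrophils are short-lived phagocytes of the innate immune system. In ATAC-seq the Tn5 transposase inserts sequencing adapters into open chromatin, so the reads at a site report how accessible it was. The 4 libraries fell into 2 groups, with 2 libraries from Morrbid-deficient cells on a C57BL6 background (KO) and 2 from wild-type cells (WT). Morrbid is a long non-coding RNA gene on chromosome 2. The series title ties it to Bim, the pro-apoptotic BH3-only protein encoded by Bcl2l11, and to the lifespan of short-lived myeloid cells. The comparison of KO with WT therefore addressed where open chromatin differed without Morrbid, first at Morrbid and Bcl2l11 and then across the genome. The deposited table held a normalised signal for 23595 consensus peaks, with a median length of 571 bp. Taking the step between values of a library as 1 read, reads in peaks numbered 6182922 and 7930547 in KO replicates 1 and 2, and 3577922 and 3803711 in WT replicates 1 and 2. Depth therefore followed genotype. The labels describe 50000 cells of each genotype transposed in duplicate and mention no separate animals, so p-values measure only the spread between these libraries, which may be technical. Values below are the mean deposited signal ± SD (n = 2 libraries per genotype), and log2 fold changes are KO over WT on the log2(signal + 1) scale with limma's adjusted p. Counting intervals cover counting error only.

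Both intronic peaks of Morrbid were lost in KO. Morrbid was listed in the table under its older symbol, Gm14005, and lies on the minus strand with its transcription start site (TSS) at position 128255087 of chromosome 2 in mm9, as the deposited distances place it. The first intronic peak, at 128159688 to 128160093, had a signal of 160.2 ± 8.03 in WT and 0.788 ± 0.1345 in KO (log2 fold change -6.50, SE 0.476, adjusted p = 3.14e-09). It held 224 reads over both WT libraries and 2 over both KO libraries, a depth-adjusted ratio of 206.1 with a 95% interval from 56.39 to 1712. The second, at 128199719 to 128200105, fell from 120.02 ± 0.459 to 0.788 ± 0.1345 (log2 fold change -6.08, SE 0.508, adjusted p = 2.95e-08). Its 168 WT reads stood against 2 KO reads, a ratio of 154.6 with a 95% interval from 42.13 to 1287. Each KO library is listed at 1 read in these peaks, which was the lowest value in the KO columns and may stand for 0. The other 5 peaks assigned to Morrbid lie upstream of its TSS, from -16222 to -64654 bp. None of these 5 passed the test, and their log2 fold changes ran from -0.24 to 0.02. The nearest retained peaks on either side ended at 128043279 and began at 128271081. No peak of the table overlaps the Morrbid TSS, the nearest being centred 16222 bp away, so accessibility of the promoter itself was not measured. The libraries labelled KO thus both lacked signal inside the Morrbid gene. Deleted DNA would also give no reads, so a deletion cannot be told apart from closed chromatin at these peaks.

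**Figure D1:**
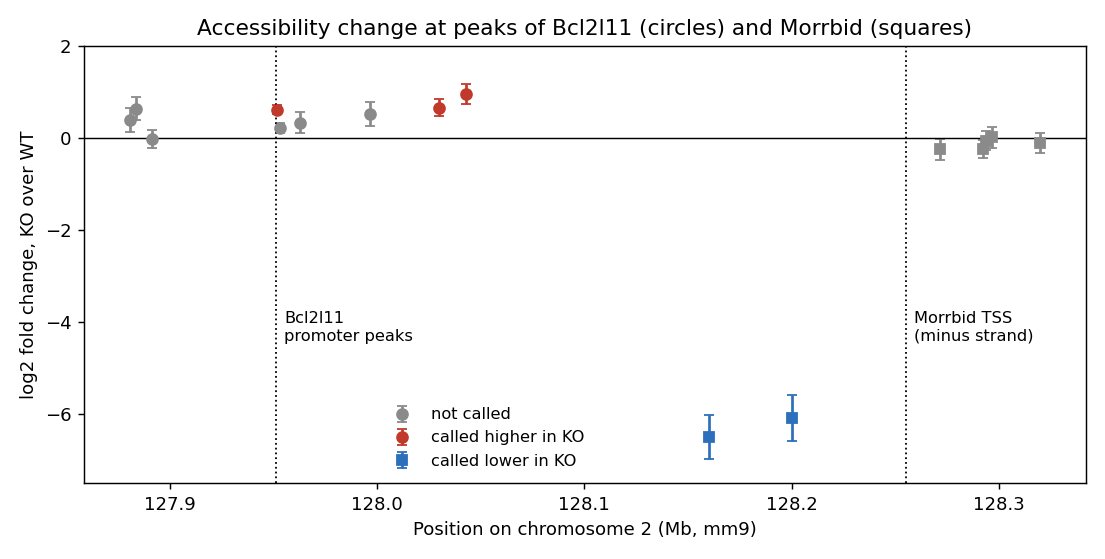
Log2 fold change in ATAC-seq signal (KO over WT, y axis) of each peak assigned to Bcl2l11 (circles) or Morrbid (squares) by position on chromosome 2 in Mb, mm9 (x axis). Bars are the model's standard error, and dotted lines mark the start of the first Bcl2l11 promoter peak and the Morrbid TSS. The 2 intronic Morrbid peaks lie at -6.50 and -6.08, and the 3 Bcl2l11 peaks called higher lie at 0.62, 0.66 and 0.95.

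At Bcl2l11, 3 of 9 assigned peaks gained accessibility in KO and none lost it. The promoter peak at the upstream start site, 127951291 to 127952184, rose 1.53-fold from 442 ± 39.99 to 678 ± 44.6 (log2 fold change 0.62, SE 0.106, adjusted p = 0.000586). The neighbouring promoter peak at 127952894 to 127953781, which lies closest to an annotated TSS (26 bp) and was therefore the one chosen to represent the gene, had a signal of 514 ± 66.6 in WT and 598 ± 23.06 in KO and did not pass (log2 fold change 0.22, SE 0.108, adjusted p = 0.185). An intergenic peak 76541 bp downstream of the TSS, at 128029619 to 128030086, rose from 115 ± 12.87 to 182 ± 15.68 (log2 fold change 0.66, SE 0.184, adjusted p = 0.0226). A second, 89772 bp downstream at 128042887 to 128043279, rose from 68.1 ± 13.67 to 132 ± 11.54 (log2 fold change 0.95, SE 0.225, adjusted p = 0.00796). It was the last peak before the lost Morrbid peaks. Of the 9 peaks, 8 had a positive log2 fold change, and the median was 0.52. Adjusted over these 9 peaks alone, 4 were higher. The peaks at 127880603, 127883718 and 127891186 lie in an intron of Acoxl and were assigned to Bcl2l11 by the nearest TSS. Of these, the peak at 127883718 (log2 fold change 0.64) passed over the 9 alone (limma adjusted p = 0.042) but not over all peaks (0.105). The upstream promoter lies 303.4 kb from the Morrbid TSS. Without KO replicate 2 the upstream promoter peak missed the threshold (log2 fold change 0.55, adjusted p = 0.0522), as it did in limma without a mean-variance trend (adjusted p = 0.13), while without WT replicate 2 the peak nearest the TSS passed (log2 fold change 0.36, adjusted p = 0.0124). The downstream calls were lost without either KO library. In the order above, their log2 fold changes were 0.75 and 1.04 without KO replicate 1, and 0.57 and 0.86 without KO replicate 2. Here and below, a fit with a lone KO library takes its spread from the WT pair alone. A call lost in such a fit need not mean a smaller change.

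**Figure D2:**
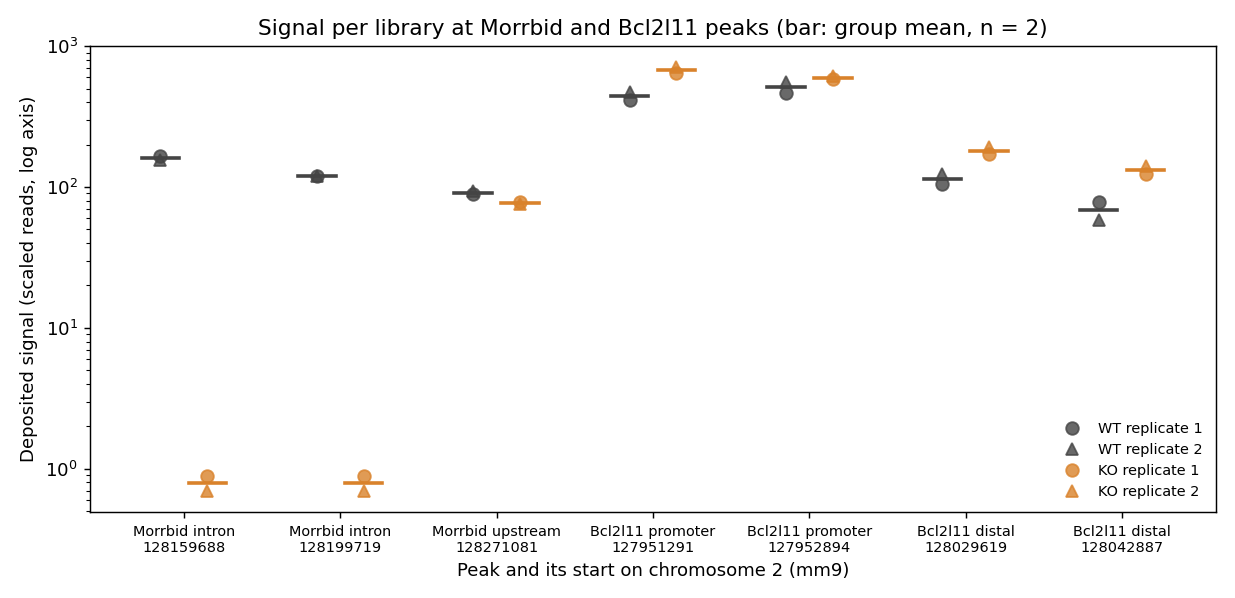
Deposited signal per library (y axis, log scale) at 7 peaks of the Morrbid and Bcl2l11 loci, named on the x axis by their start on chromosome 2 in mm9. Circles are replicate 1, triangles replicate 2, and horizontal bars group means (n = 2). At the upstream Bcl2l11 promoter peak (127951291) both KO libraries lie above both WT libraries, with means of 678 and 442, and at the intronic Morrbid peaks the KO mean is 0.788.

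The wider region held 1 further gain. The 40 peaks within 1000 kb of the Morrbid TSS, leaving out those of Morrbid, had a median log2 fold change of 0.04, at the 57.18th percentile of 10000 random runs of as many neighbouring peaks elsewhere in the genome, with 4 higher and 0 lower. Beside the 3 at Bcl2l11, the gain was an intergenic peak at 129068095 assigned to A730036I17Rik, 813.48 kb from the Morrbid TSS, which rose from 177.7 ± 26.87 to 347 ± 46.67 (log2 fold change 0.97, adjusted p = 0.000279). Within 500 kb, 13 peaks had a median of 0.39, at the 99.22nd percentile. Without the 9 Bcl2l11 peaks, the remaining 4 had a median of 0.08. Among the fixed list of chromosome 2 neighbours, 19 genes had a promoter peak, of which 0 rose, 1 fell and 18 were not called (1 lower adjusted over the list alone, camera's adjusted p = 0.949). Bcl2l11 stood in this list with its peak nearest a TSS and not with its upstream promoter peak, which was called higher. The median of the list turned from -0.02 to 0.04 under median centring. The promoter that fell was that of Itpripl1, at 126968961 to 126969314, with a signal of 92.9 ± 0.559 in WT and 38.04 ± 0.0953 in KO (log2 fold change -1.27, SE 0.266, adjusted p = 0.00321). Apart from Bcl2l11, the listed promoters nearest to the Morrbid TSS were those of Anapc1, Tmem87b, Zc3h8, Zc3h6 and Bub1. They had log2 fold changes of 0.01, 0.16, -0.05, 0.20 and -0.08 and did not pass. The Anapc1 promoter, at 257.97 kb, lies nearer to the Morrbid TSS than the Bcl2l11 promoters do. Hypk, matched through an older symbol of the list, lies at 121282463 on chromosome 2 and is no neighbour of Morrbid.

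Across the genome, 1434 peaks were higher and 1074 lower in KO among 23595 tested. Gains were more frequent and smaller, with a median log2 fold change of 0.49 (1.404-fold) against -0.80 (1.741-fold) among losses. Only 88 gains but 289 losses reached 2-fold. The gains with the lowest p lay at the promoters of Opn3, Suco, Ripk2, Mplkip, Lnpep, Kansl1l and Bard1, and at 2 peaks downstream of Lyz2, the lysozyme gene of neutrophils and macrophages. Opn3, encoding an opsin, rose from 1636 ± 24.52 to 2429.7 ± 11.85 at 177622234 to 177623711 of chromosome 1 (log2 fold change 0.57, SE 0.0594, adjusted p = 1.65e-06). Ripk2, the kinase downstream of the NOD receptors, rose from 1829 ± 153.4 to 2579.5 ± 76.33 at 16090260 to 16091458 of chromosome 4 (log2 fold change 0.50, adjusted p = 1.49e-05). The Lyz2 peak at its transcription end, 116713696 to 116715020 of chromosome 10, rose from 287 ± 6.731 to 614 ± 37.31 (log2 fold change 1.09, SE 0.115, adjusted p = 1.67e-06). The adjoining intergenic peak at 116712684 rose from 129.6 ± 15.97 to 309.9 ± 3.654 (log2 fold change 1.26, adjusted p = 1.82e-05). An intergenic peak 9275 bp from Epgn, an EGF family ligand, rose from 46.8 ± 18.45 to 169.7 ± 0.974 (log2 fold change 1.89, adjusted p = 3.16e-05). The remaining gains of this rank were intergenic peaks assigned to Cdkl4 (0.99) and, 674605 bp from its TSS, to 1700019E08Rik (0.70).

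The loss with the lowest p was an intergenic peak in a simple repeat, 39447 bp from the TSS of the collagen prolyl hydroxylase gene P4ha2. At 53953531 to 53954215 of chromosome 11 it fell from 1658 ± 33.88 to 417 ± 29.97 (log2 fold change -1.99, SE 0.0877, adjusted p = 3.43e-14). Next in rank were the Morrbid peaks and a peak at -34736 bp from the TSS of Apbb1ip, an adaptor of integrin activation, which fell from 454 ± 41.26 to 117.6 ± 5.185 (log2 fold change -1.94, adjusted p = 6.49e-09). The others of this rank were assigned to Fam174a, Ndufb3, Pisd-ps1, Gm13154, Smc5, Ntpcr, C130026I21Rik and Nova1, with log2 fold changes from -2.36 to -1.48. The deposited annotation places the peaks of Fam174a, Pisd-ps1, Gm13154, Smc5, Ntpcr, C130026I21Rik and Nova1 in repeats, including satellite sequence for Smc5 and Nova1. Reads in such peaks may be shared with near-identical copies, so their position is uncertain. Among promoters, the largest losses were at Pprc1 (log2 fold change -1.97), Abcg1 (-1.61), Rnf135 (-1.56), Gcnt4 (-1.54) and 6430706D22Rik (-1.52). Rnf135 lies in the 1 Mb window at 79 Mb of chromosome 11, where 10 of 19 peaks fell. The largest promoter gains were at Fgfr1op (1.64), Ifi47 (1.31), Ugt1a6a (1.125), Gm21586 (0.93) and Ccl27a (0.89), and all 5 calls were lost when either KO library was left out, with adjusted p of 0.478, 0.703, 0.246, 0.197 and 0.0522 in that order without KO replicate 1 and 0.373, 0.152, 0.589, 0.102 and 0.188 without KO replicate 2. Rnf135 was lost without KO replicate 1 (adjusted p = 0.21).

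**Figure D3:**
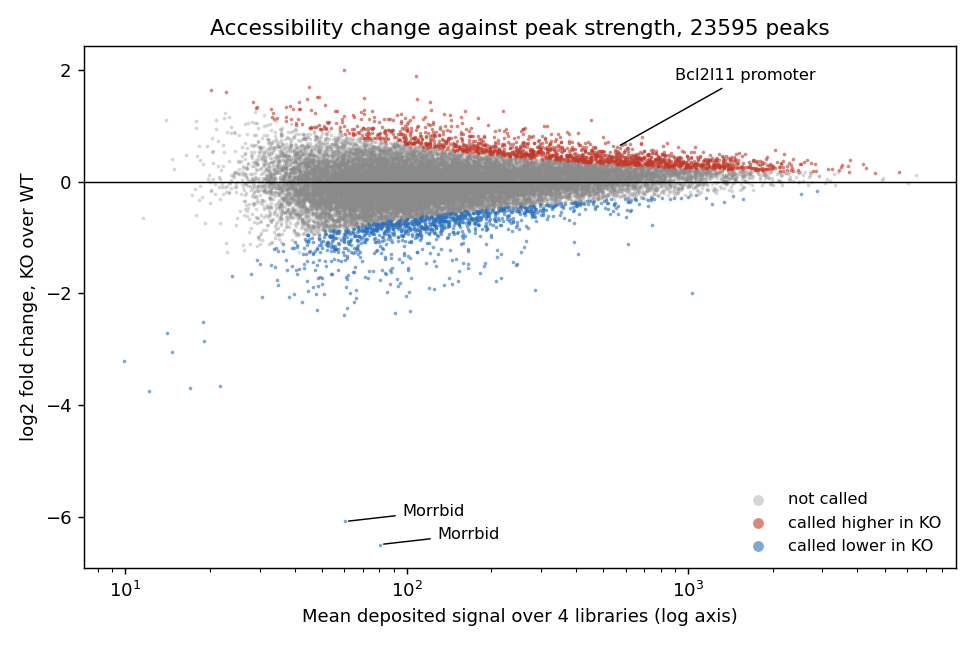
Log2 fold change (KO over WT, y axis) against mean deposited signal over the 4 libraries (x axis, log scale), with a point for each of 23595 peaks. Red points are the 1434 peaks called higher and blue points the 1074 called lower. Gains gather among the strongest peaks, where 585 of them fall in the top decile, while losses are spread over the other strengths, with 149 in the sixth decile and 47 in the tenth. The 2 intronic Morrbid peaks stand apart at -6.50 and -6.08.

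Peak strength and scaling shaped these totals. The median log2 fold change was -0.11 in the second decile of mean signal and 0.15 in the tenth, and 585 of the 1434 gains fell in the tenth. Gains made up 57.18% of calls as deposited, 74.31% after median centring (2248 higher, 777 lower) and 39.99% after scaling to the total over peaks (879 higher, 1319 lower). These 2 scalings move all peaks nearly alike, taking the median log2 fold change of all peaks from -0.00189 to 0.0649 and to -0.0564, so the sign of a list median near 0, given below, turns with that shift alone. Cyclic loess, which removes a trend with strength, left 807 higher and 888 lower. The counts fell to 276 higher and 312 lower without KO replicate 1 and to 185 and 237 without KO replicate 2, and rose to 2610 and 2189 without WT replicate 1 and to 2250 and 1580 without WT replicate 2. In limma without a mean-variance trend 0 peaks were higher, against 3232 with a positive change at an unadjusted p under 0.05 in the test with the trend, and 22 were lower. In 55.28% of peaks both KO libraries lay on the same side of both WT libraries, where chance gives 33.33%.

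Promoters made up 24.47% of tested peaks, 31.1% of gains and 27.84% of losses. By Fisher's exact test (two-sided) the odds ratio was 1.426 for gains (95% interval 1.267 to 1.603, adjusted p = 3.37e-08 over 8 annotation classes) and 1.201 for losses (1.044 to 1.379, adjusted p = 0.0197). The excess among gains reversed under cyclic loess, to an odds ratio of 0.6166, and the excess among losses reversed without KO replicate 1, to 0.6868, and without KO replicate 2, to 0.8028. By the same Fisher's exact test, median centring left 1.072 among losses (p = 0.396), leaving out WT replicate 1 left 1.089 among gains (p = 0.074), and leaving out WT replicate 2 left 1.103 among losses (p = 0.102). Introns held 32.42% of tested peaks but 27.06% of gains and 25.79% of losses. By chromosome, the median log2 fold change was lowest on chromosome 11 (-0.13), with 58 gains and 145 losses, and highest on chromosome 13 (0.11), with 115 gains and 25 losses.

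Most promoters of apoptosis genes were not called, as held for all 8777 promoter peaks, of which 674 rose and 512 fell. Of 10 pro-apoptotic BCL2 family promoters, 1 rose, 1 fell and 8 were not called (1 and 2 adjusted over the list alone, camera's adjusted p = 0.937). Bcl2l11 entered this list with its peak nearest a TSS, which was not called. Its upstream promoter peak, called higher (log2 fold change 0.62), was left out of the list and of its tests. Bnip3l, a mitochondrial BH3-like protein with a role in mitophagy, rose from 741 ± 0.5004 to 921 ± 41.5 (log2 fold change 0.31, adjusted p = 0.0208). Bax, an effector of mitochondrial permeabilisation, fell from 229 ± 7.593 to 155 ± 6.708 (log2 fold change -0.56, adjusted p = 0.0253). Bmf had a log2 fold change of -0.57 and did not pass (adjusted p = 0.0718). None of 6 anti-apoptotic promoters passed over all peaks (camera's adjusted p = 0.937), and 2 were higher adjusted over the list alone, namely Bcl2a1d and Bcl2, with log2 fold changes of 0.66 and 0.37. Of 22 promoters of death receptors and caspases, 1 rose and 21 were not called (1 adjusted over the list alone, camera's adjusted p = 0.949), and the median of the list turned from -0.02 to 0.05 under median centring. The promoter that rose was that of Casp2, an initiator caspase, from 365 ± 24.69 to 484 ± 1.383 (log2 fold change 0.41, adjusted p = 0.0239). Fry's directional test passed for the pro-apoptotic list, downward (adjusted p = 0.027), and for the anti-apoptotic list, upward (adjusted p = 0.016), while camera did not call either (adjusted p = 0.937 for both). Bnip3l and Casp2 missed the threshold under cyclic loess (adjusted p = 0.213 and 0.0845) and total scaling (0.0561 and 0.0523). Without KO replicate 1 or 2 the adjusted p was 0.157 or 0.393 for Bnip3l, 0.174 or 0.298 for Bax and 0.246 or 0.286 for Casp2.

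Promoters of neutrophil genes were likewise mostly not called. Of 16 promoters of secondary and tertiary granule genes, 2 rose, 1 fell and 13 were not called (3 and 2 adjusted over the list alone, camera's adjusted p = 0.937). Lyz2 rose from 311 ± 29.83 to 505 ± 62.55 at its promoter (log2 fold change 0.70, adjusted p = 0.000832). Padi4, the enzyme that citrullinates histones, fell from 227 ± 27.7 to 124 ± 21.04 (log2 fold change -0.87, adjusted p = 0.00275). Of 5 promoters of primary granule and promyelocyte genes, 1 rose and 4 were not called (1 higher and 1 lower adjusted over the list alone, camera's adjusted p = 0.949). It was that of the granule protease activator Ctsc (log2 fold change 0.37, adjusted p = 0.0303), and the call was lost under cyclic loess (0.195), total scaling (0.0747), and without KO replicate 1 (0.146), KO replicate 2 (0.239) or WT replicate 2 (0.248). Of 32 promoters of mature neutrophil genes, 0 rose, 4 fell and 28 were not called (0 and 4 adjusted over the list alone, camera's adjusted p = 0.937). These were Csf3r, the G-CSF receptor (162 ± 19.19 to 92.8 ± 4.863, log2 fold change -0.79, adjusted p = 0.0112), the pattern receptor Tlr2 (-0.79, 0.0114), the marrow retention receptor Cxcr4 (-0.29, 0.0168) and the integrin chain Itgb2 (-1.035, 0.0227). Under median centring Cxcr4 was no longer called (adjusted p = 0.0562) and 2 other mature neutrophil promoters were higher. Under total scaling the medians of the primary and the later granule genes turned from 0.05 and 0.03 to -0.00268 and -0.0224. Without KO replicate 1 the adjusted p was 0.102 for Padi4, 0.0803 for Csf3r, 0.305 for Tlr2, 0.167 for Cxcr4 and 0.363 for Itgb2. Without KO replicate 2 it was 0.0953 for Lyz2, 0.168 for Csf3r, 0.259 for Cxcr4 and 0.058 for Itgb2.

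Most promoters of myeloid regulators were not called either, and the split of the calls depended on scaling. Of 30 myeloid transcription factor promoters, 2 rose, 2 fell and 26 were not called (7 and 5 adjusted over the list alone, camera's adjusted p = 0.949), and the median turned from 0.04 to -0.02 under total scaling. The calls were 6 higher and 2 lower under median centring and 0 and 4 under cyclic loess. Atf3, a stress-induced factor, fell from 736 ± 41.08 to 473 ± 28.02 (log2 fold change -0.64, SE 0.101, adjusted p = 0.000266), and Cebpb, the factor of emergency granulopoiesis, fell from 761 ± 57.33 to 579 ± 35.69 (log2 fold change -0.39, adjusted p = 0.011). Klf5 and Cebpg rose (log2 fold changes 0.32 and 0.29, adjusted p = 0.00754 and 0.0491), but not under cyclic loess (0.221 and 0.372). Of 33 promoters of cytokine receptors and JAK-STAT signalling, 2 rose, 4 fell and 27 were not called (4 and 5 adjusted over the list alone, camera's adjusted p = 0.937), against 5 higher and 3 lower under median centring and 1 and 3 under cyclic loess. The promoter of Il6ra, the IL-6 receptor chain, fell from 248 ± 6.268 to 138 ± 24.16 (log2 fold change -0.85, adjusted p = 0.00217), and its signalling partner Il6st rose from 257 ± 11.67 to 378 ± 52.44 (0.55, adjusted p = 0.011). The adjacent genes Stat5a and Stat5b fell, with log2 fold changes of -0.62 and -0.56 (adjusted p = 0.0306 and 0.0411). Ifngr1 rose (0.33, adjusted p = 0.0136). Under cyclic loess the Ifngr1 call was lost with a smaller log2 fold change (0.19, adjusted p = 0.162), while Stat5a and Stat5b missed the threshold with log2 fold changes of -0.58 and -0.55 (0.0569 and 0.064). Without KO replicate 1 the adjusted p was 0.242 for Cebpb, 0.0698 for Klf5, 0.403 for Cebpg, 0.349 for Il6st, 0.246 for Stat5a, 0.244 for Stat5b and 0.208 for Ifngr1. Without KO replicate 2 it was 0.0787 for Cebpb, 0.221 for Klf5, 0.232 for Cebpg, 0.116 for Il6ra, 0.242 for Stat5a, 0.257 for Stat5b and 0.227 for Ifngr1. Cebpg was also lost without WT replicate 1 (0.22) and under total scaling (0.116), Stat5a and Stat5b without WT replicate 2 (0.0547 and 0.22), and Stat5b under median centring (0.0658). The Atf3 call held without each library in turn.

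Among Polycomb subunit genes the called promoters were all losses, while peaks farther from the TSS went both ways. Of 23 promoters of PRC2 and PRC1 subunits, 0 rose, 4 fell and 19 were not called (1 higher and 4 lower adjusted over the list alone, camera's adjusted p = 0.949). The fixed list also holds the demethylase genes Kdm6a and Kdm6b, which encode no subunit. The promoter of Ring1, a ubiquitin ligase of PRC1, fell from 194 ± 34.13 to 99.7 ± 1.103 (log2 fold change -0.95, SE 0.189, adjusted p = 0.0023). Those of the PRC2 genes Ezh1 (-0.69, 0.0154), Phf19 (-0.81, 0.0154) and Suz12 (-0.68, 0.0162) also fell, in log2 fold change and adjusted p. Suz12 lies in the 1 Mb window at 79 Mb of chromosome 11, where 10 of 19 peaks fell, with a median of -0.68. Ezh1 lies on the same chromosome, which had the lowest median, with 58 gains and 145 losses. A regional change was not told apart from one at these 2 promoters. All 4 losses were among the calls under median centring, total scaling and cyclic loess, although median centring also called 2 promoters of the list higher and turned its median from -0.00516 to 0.06. Without KO replicate 1 the adjusted p was 0.154 for Ezh1, 0.395 for Phf19 and 0.361 for Suz12, and without KO replicate 2 it was 0.176 for Ezh1. Over all 47 peaks of the listed genes, 2 rose and 6 fell. The gains were intronic peaks of Phf19, 8890 bp from the TSS (0.37, adjusted p = 0.01), and Pcgf5 (0.29, 0.0266), chosen after the values were seen, and neither was called under cyclic loess (0.101 and 0.306), without KO replicate 1 (0.175 and 0.445) or without KO replicate 2 (0.203 and 0.144). Of the developmental transcription factors classically bound by Polycomb, only 2 of 120 had a promoter peak, those of Dlx1 and Hoxb4, and neither passed.

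Inflammatory and stress gene promoters were also mostly not called. Of 23 inflammatory and NF-kB promoters, 2 rose, 2 fell and 19 were not called (3 and 2 adjusted over the list alone, camera's adjusted p = 0.949). The NF-kB subunit genes Relb (671 ± 18.09 to 914 ± 40.48, log2 fold change 0.45, adjusted p = 0.00213) and Nfkb1 (0.54, 0.0165) rose, and Rela fell (160.4 ± 15.2 to 92.03 ± 4.728, -0.79, 0.0109), as did Marcksl1 (-0.38, 0.0361). Of 24 immediate early gene promoters, 1 rose, 2 fell and 21 were not called (3 and 4 adjusted over the list alone, camera's adjusted p = 0.937). Under median centring the medians of the inflammatory and immediate early lists turned from -0.05 and -0.06 to 0.02 and 0.01. Jun rose from 3364 ± 147.6 to 4079 ± 34.07 (log2 fold change 0.28, adjusted p = 0.000552) and Dusp1 fell (-0.26, 0.0163), beside Atf3. Under cyclic loess the Jun call was lost (adjusted p = 0.537) and camera called the immediate early list lower (adjusted p = 0.0461, against 0.937 as deposited), with 0 of its promoters higher and 6 lower. With the replicate block added, camera's adjusted p = 0.00998, with 1 higher and 8 lower, while median centring gave 3 higher and 1 lower. With the trends on strength and neighbourhood removed camera did not call the list (adjusted p = 0.374), nor did it under cyclic loess with an estimated correlation, without the block (0.771) or with it (0.833). None of 26 interferon-stimulated promoters passed over all peaks or adjusted over the list alone (median -0.11, camera's adjusted p = 0.937). Without KO replicate 2 the adjusted p was 0.135 for Relb, 0.144 for Nfkb1, 0.168 for Rela, 0.208 for Marcksl1 and 0.135 for Dusp1, and without KO replicate 1 it was 0.23 for Nfkb1, 0.0812 for Rela, 0.385 for Marcksl1 and 0.327 for Dusp1. Under median centring Marcksl1 and Dusp1 missed the threshold (0.0724 and 0.0602), as did Marcksl1 without WT replicate 2 (0.0646).

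Of 34 cell cycle promoters, 2 rose, 1 fell and 31 were not called (2 and 1 adjusted over the list alone, camera's adjusted p = 0.937). Cdkn1b, the cell cycle inhibitor p27, rose from 1264 ± 45.56 to 1558 ± 0.2808 (log2 fold change 0.30, adjusted p = 0.00642), and Cdk4 rose from 183 ± 19.98 to 262 ± 6.287 (0.52, 0.0285). Cdkn2a, encoding a further inhibitor, fell from 236 ± 20.44 to 154 ± 27.97 (-0.62, 0.0197). Over all 8777 promoter peaks, 1 per gene, 674 rose and 512 fell, which is the background for the counts of every list. Of 23 control genes with ubiquitous promoters, 3 rose, 1 fell and 19 were not called (4 and 2 adjusted over the list alone, camera's adjusted p = 0.937), with Tbp, Gapdh and Pgk1 at log2 fold changes of 0.53, 0.28 and 0.39 and Polr2a at -0.29. Of these control genes, only Tbp kept its call under every scaling. Polr2a lies in the 1 Mb window at 69 Mb of chromosome 11, where 10 of 33 peaks fell. Polr2a was lost under median centring (adjusted p = 0.116), Gapdh under total scaling (0.0507) and cyclic loess (0.346), and Pgk1 under cyclic loess (0.0966). The median of the control genes turned from 0.03 to -0.0257 under total scaling and to -0.0903 under cyclic loess. Cdkn1b was lost under cyclic loess (adjusted p = 0.251) and Cdk4 under total scaling and without WT replicate 2 (0.0535 for both). Without KO replicate 2 the adjusted p was 0.161 for Cdkn1b, 0.322 for Cdk4, 0.407 for Cdkn2a, 0.203 for Tbp, 0.365 for Gapdh, 0.165 for Pgk1 and 0.287 for Polr2a, and without KO replicate 1 it was 0.141 for Cdkn1b, 0.228 for Cdk4, 0.0911 for Tbp, 0.134 for Gapdh, 0.337 for Pgk1 and 0.35 for Polr2a. Polr2a was also lost without WT replicate 1 (0.16).

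Markers of other marrow cells had few promoter peaks. None of the promoters of B cell (2 with a peak), T cell (1), NK cell (0), eosinophil (0), basophil and mast cell (2), monocyte and macrophage (4), dendritic cell (5), erythroid (4), megakaryocyte and platelet (1) or stem and progenitor cell (7) markers passed over all peaks. Camera gave an adjusted p of 0.949 for each of the monocyte, dendritic cell, erythroid and stem cell markers, and the other 6 lists were too small to test. Over all peaks assigned to these genes, 3 of 57 peaks of stem and progenitor cell markers rose and 1 fell, as did 2 and 0 of 20 for basophil and mast cells, 1 and 0 of 14 for B cells, 1 and 0 of 14 for T cells and 0 and 1 of 14 for erythroid cells, with none called for the other 5 types. The gains were distal peaks assigned to Kit (log2 fold change 0.51, on both lists), Erg (0.48), Meis1 (0.47), Cd200r3 (0.62), Bank1 (1.61) and Trat1 (0.37), and the loss was at Tal1 (-0.59, on both lists). All 6 gains were lost as calls without either KO library, with adjusted p of 0.208, 0.193, 0.298, 0.0608, 0.305 and 0.158 in that order without KO replicate 1 and 0.228, 0.374, 0.303, 0.478, 0.464 and 0.477 without KO replicate 2. The Tal1 call was lost without KO replicate 1 (adjusted p = 0.285), KO replicate 2 (0.295) or WT replicate 2 (0.18), under median centring (0.0729) and under cyclic loess (0.0847). These distal peaks were chosen after the values were seen. Adjusted over each list alone, 1 basophil and mast cell promoter and 1 megakaryocyte promoter were lower. Among 13 promoters of neutrophil markers, 0 rose and 1 fell, that of Csf3r (1 higher and 1 lower adjusted over the list alone, camera's adjusted p = 0.937). The Csf3r call was lost without KO replicate 1 (adjusted p = 0.0803) and KO replicate 2 (0.168). With limma's camera, 0 of the 20 lists with at least 3 promoter peaks passed, 0 had an unadjusted p under 0.05, and the lowest adjusted p was 0.937, or 0.954 with an estimated correlation. Fry, which tests the members without comparing them with other genes, passed 2 lists in a common direction and 16 for change in either direction. The sign of camera's direction differed from that of the median for the chromosome 2 neighbours (median -0.02), death receptors and caspases (-0.02) and dendritic cell markers (-0.11).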

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

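The settings below were fixed before the data were examined, except thinning, trend removal, leaving out repeat peaks and camera with an estimated correlation under cyclic loess. Both intronic Morrbid peaks stayed lower in every setting that tested them; the filter on the upper 50% of peaks by mean removes them and gives no value. The count tests planned for whole-number data (a negative binomial test and limma-voom) were not run: the values are whole multiples of a step, but too few are low enough to show that a step is 1 read, so they were kept as a signal; and the planned run without a low filter changes nothing because the filter removed no peak. The cause of the following changes was not tested unless stated. Gains numbered 2202 and losses 1852 at adjusted p below 0.1, and 88 and 289 with at least 2-fold change, by construction. Gains numbered 2248 under median centring, 879 under total scaling, 807 under cyclic loess and 840 with both trends removed. The upper filter left 612 losses. In limma without trend 0 gains and 22 losses remained, and the upstream Bcl2l11 promoter kept its log2 fold change of 0.6169 but not its call. The odds ratio of promoters among gains turned to 0.6166 under cyclic loess, 0.6642 under the replicate block with cyclic loess, 0.9864 under the upper filter and 0.6131 with both trends removed, and could not be had without trend. Among losses it was 1.072 under median centring, 0.9983 under the upper filter and 0 without trend. Cyclic loess called 1 gene list, with and without the block, and 0 with an estimated correlation. The region within 500 kb of Morrbid had a median of 0.3902, at the 99.22nd percentile of random runs. A Nfkbiz peak called higher turned from 0.1793 to -0.03413 under cyclic loess, with and without the block.

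Leaving out each library in turn gave 185 to 2610 gains, 237 to 2189 losses, 0.5247 to 0.7091 for the upstream Bcl2l11 promoter, 0.09232 to 0.357 for the Bcl2l11 peak nearest the TSS, and odds ratios of 1.089 to 1.889 for promoters among gains and 0.6868 to 1.382 among losses. The lone library of a genotype is then assumed to vary like the other genotype, and the lower counts followed the loss of a KO library. Of 72 named peaks that were called, 37 kept the call without KO replicate 1, 39 without KO replicate 2, 70 and 69 without WT replicates 1 and 2, 62 under cyclic loess, 67 after thinning, 58 with both trends removed and 9 without trend, and none reversed. Peaks chosen later held less well. Of 138 such calls, 49 were kept without KO replicate 1, 28 without KO replicate 2, 97 under cyclic loess (with 1 reversed, at Nfkbiz), 113 after thinning and 4 without trend. Thinning to equal reads left 1283 gains and 989 losses, of which 1164 and 843 were shared with the calls at full depth.

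Replicate numbers are shared between the genotypes, but replicate differences in KO and WT correlated at -0.0392 over peaks, so the numbers were not taken to pair the libraries. With the replicate block 1656 peaks were higher and 1279 lower, including all 1434 and 1074 of the test without it. The slope of the log2 fold change on mean log2 signal was 0.0588, against 0.0224 between the KO libraries and 0.00526 between the WT libraries, and 0.0612 after thinning. At matched strength, promoters had a median log2 fold change below that of distal peaks by -0.143 (95% bootstrap interval -0.157 to -0.13). This interval, like the bootstrap and permutation values below, treats peaks of the same 4 libraries as independent and holds no spread between libraries. WT depth limits weak peaks, since a median WT peak held 86 or 91 reads.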

Other observations

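The tests in this part were chosen after the results they bear on had been seen, except that of the other peaks around the histone genes. Distal peaks outside the rule for named peaks, chosen after their values were seen, changed in both directions at neutrophil genes. Over all peaks assigned to mature neutrophil genes, 7 rose and 8 fell of 139, and 4 of these losses were the promoter peaks named above. For secondary and tertiary granule genes, promoters included, 8 rose and 2 fell of 48. Among all tested peaks 6.08% rose and 4.55% fell. Camera over all assigned peaks called neither list (adjusted p = 0.751 and 0.8). The peak at the transcription end of S100a9, a calcium-binding protein abundant in neutrophils, rose from 843 ± 84.14 to 1284 ± 72.38 (log2 fold change 0.61, limma adjusted p = 5.03e-05) at 90495523 to 90497546 of chromosome 3. All 3 Lyz2 peaks rose under each scaling and under cyclic loess. A peak 21499 bp from Fasl, the ligand of the death receptor Fas, rose from 387 ± 6.44 to 625 ± 27.89 (0.69, adjusted p = 0.000217), a peak at -9172 bp from the activation marker Cd69 rose from 246 ± 9.96 to 442 ± 5.793 (0.84, adjusted p = 0.000145), and an intronic peak at -5066 bp from the anti-apoptotic Bcl2l10 rose from 147 ± 6.506 to 279 ± 23.12 (0.92, adjusted p = 0.000532). The calls at S100a9, Fasl, Cd69 and Bcl2l10 held without each library in turn, while that at the Lyz2 promoter was lost without KO replicate 2 (adjusted p = 0.0953). A weaker S100a9 peak, at 90487992, fell (-0.74, adjusted p = 0.0431), and missed the threshold under cyclic loess at a similar log2 fold change (-0.64, adjusted p = 0.0925). Distal peaks also fell at the inflammasome gene Nlrp3 (-0.78, adjusted p = 0.00271), at Retnlg (-0.69, 0.0199), at the Fc receptor gene Fcgr4 (-0.88, 0.0211) and at Chil3 (-0.51, 0.0263). Without KO replicate 2 these 4 were no longer called (adjusted p = 0.0707, 0.251, 0.215 and 0.149).

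Mcl1, the anti-apoptotic gene on which neutrophil survival depends, had 4 peaks, of which 3 fell, all upstream of the promoter. The peak at 95454290 to 95455727 of chromosome 3 fell from 504 ± 4.77 to 359.9 ± 23.0 (log2 fold change -0.49, limma adjusted p = 0.00759), and those at 95449375 and 95455994 had log2 fold changes of -1.17 and -0.63. Under median centring and under cyclic loess 2 of the 3 passed, and all 3 missed the threshold without KO replicate 1 (adjusted p = 0.0571, 0.338 and 0.297 in that order). By assignment to the nearest TSS, genes with the most gained peaks were Inhba, encoding an activin subunit (5 of 19), Hgf, the hepatocyte growth factor gene (4 of 14), Lmo4 (4 of 18), Mospd2 (4 of 6) and Wwox (4 of 16). Most calls of Inhba, Hgf and Lmo4 were lost without KO replicate 2, with adjusted p of 0.28 and 0.302 at 2 of the Inhba peaks. By the same assignment, genes with the most lost peaks were Gm13154 (10 of 10), Hnf4g (8 of 9), Gm3763 (7 of 7) and Gm21950 (6 of 6). The Hnf4g losses lay at -306848 to -491106 bp from its TSS, and most Gm13154 losses in introns of Zfp982. The lost peaks need not belong to the genes named. Of the peaks with at most 3 reads in each KO library and at least 10 in each WT library, 2 were the Morrbid peaks and 3 lay elsewhere, all in young repeats: an intron of Ppm1h, 150019 bp from Mirlet7i to which it was assigned, an intron of Thsd7b, and a site at -55065 bp from Trib2 (log2 fold changes -3.75, -3.70 and -3.20).

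Bcl2l11 was the locus of interest, and technical explanations of its gain were set against the data. The 9 assigned peaks, which include those in the Acoxl intron, had a median log2 fold change of 0.52. It lay at the 99.71st percentile of 10000 runs of 9 neighbouring peaks elsewhere, of which 95% lay between -0.454 and 0.344. This argues against ordinary regional variation. With the trends on strength and neighbourhood removed the upstream promoter peak stayed at 0.526 (limma adjusted p = 0.00342). It was 0.617 as deposited, so these trends account for a small part of the gain. After thinning to equal reads it stood at 0.612 (limma adjusted p = 0.000257). Thinning keeps the expected fold change, so this shows only that the call did not need the extra KO reads. Depth followed genotype, so its effect on the fold change cannot be told apart from that of genotype. A library preparation that differed between the genotypes remains open, because each genotype was prepared once in duplicate as far as the labels say. An effect of losing Morrbid on its neighbour is a hypothesis that may fit these values, and it was not tested beyond the comparison of genotypes. Loss of the RNA cannot be told apart here from loss of DNA in the Morrbid gene.

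Promoters of replication-dependent histone genes were the only one of 87 groups of promoters sharing a symbol stem (at least 10 members) to pass camera at the preset correlation (adjusted p = 8.32e-11, but adjusted p = 0.979 with an estimated correlation). Of 36 such promoters, 17 rose and 0 fell, and all 36 had a positive log2 fold change. The median of 0.438 lay above the -0.124 to 0.1 spanned by 95% of promoter lists matched on strength. The group was picked from the 87 for its shift, so that range is no independent test. With the trends on strength and neighbourhood removed the median was 0.446, which argues against the strength trend. The median ranged from 0.383 to 0.504 over the scalings. The 17 gains lay in the chromosome 13 clusters between 21 and 24 Mb, where 29 other peaks had a median of 0.2 (bootstrap SE 0.069) against 0.448 for the 32 histone promoters, so a change across the segment cannot be told apart from one at the histone genes. A higher share of cycling cells in KO may also contribute and stays open, since the 34 cell cycle promoters had a median of 0.071 with a bootstrap interval from -0.0465 to 0.143, and near-identical histone copies can share reads.

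Among peaks in multi-copy sequence, 8 of 9 in satellites fell, with a median log2 fold change of -1.55. This lay far below the -0.321 to 0.246 spanned by 95% of lists matched on strength. The group was chosen after its values were seen, so that range is no independent test. With the trends on strength and neighbourhood removed the median was -1.51, which argues against the trend of weak peaks. By 1 Mb window, losses were densest at 146 Mb of chromosome 4 (13 of 14 peaks) and 4 Mb of chromosome X (12 of 12), each with a median of -1.58. Next were windows on chromosome 11 at 97 (11 of 22), 69 (10 of 33), 78 (10 of 17) and 79 Mb (10 of 19). Chromosome 17 at 28 Mb (10 of 23) and chromosome 5 at 136 Mb (10 of 25) followed. The windows on chromosomes 11, 17 and 5 had milder medians, from -0.367 to -0.68. The repeat content of these windows was not tested, so their losses cannot be assigned to multi-copy sequence. The log2 fold change also correlated with the number of peaks within 500 kb, at -0.179 for promoters and -0.122 for distal peaks. A candidate explanation for the satellite losses is that reads of multi-copy sequence were counted differently in the genotypes. Peaks in rRNA copies (5 of 9 lower, median -0.673) and in young repeat families (20 of 58 lower and 1 higher, -0.339) lay below 2479 peaks in other repeats (0.049). The difference was -0.51 (permutation p = 1e-05, the smallest that 100000 resamples can give). A loss of accessibility or of copies in KO would give the same values and was not tested.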
